A study of Danio rerio with 36 samples.

How the data were processed

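Whole wild-type zebrafish larvae were profiled in 12 groups of 3 libraries. Embryos were kept from 6 h after fertilisation in regular medium or in medium with 130 mM or 222 mM glucose, and after 14 days the caudal fin was removed beyond the end of the spinal cord and the larvae were returned to their medium. Total RNA was taken from uncut larvae or 3, 24 or 48 h after amputation, and paired-end libraries were sequenced on an Illumina NovaSeq, per the labels. The higher dose is in mM, as in the sample labels, though once in nM in the design text. Each medium has a single uncut group of unstated age, so amputation responses and their differences cannot be separated from time. No osmotic control group was analysed.

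The deposited table gives for each of 30221 Ensembl genes a count and an FPKM value in each library. Per the submitters' processing notes, reads were aligned with HISAT to GRCz11, and StringTie and edgeR were used. The counts, whole numbers per gene deposited by the authors, are not normalized, and the tool and strand setting behind them are not given in the sources used here. FPKM values, deposited by the authors beside the counts, are scaled to transcript length and to mapped fragments. Overlapping or antisense genes and near-identical copies may share reads, so values of gene families such as crystallins, globins, trypsinogens, cathepsins and Mx genes are uncertain for the single member, and copies with the same name are given with their identifiers. Symbols and positions are those of the deposited table, except that 3124 symbols were completed from an Ensembl name table, and 19 list members were matched through another symbol. Total counts ran from 47904694 to 67514889 per library, so the depths differed by less than 1.5 times. No 2 libraries of a group agreed within sampling noise.

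Before the data were examined, the tests were written for FPKM values with limma, because the labels name FPKM. As the table also holds counts, the main test became edgeR's quasi-likelihood test on the counts (edgeR 4.0.16, R 4.3.3; TMM scaling, robust dispersion and quasi-likelihood fits, 1 mean per group, all 36 libraries in 1 fit), and the FPKM test was kept as an alternative (limma 3.58.1). The 20120 genes with at least 1 FPKM in at least 3 libraries were tested. The common biological coefficient of variation was 0.203 and the median prior df 6.93. P-values were adjusted by the Benjamini-Hochberg method within each comparison, a gene changed at an adjusted p under 0.05 with no minimum fold, and standard errors are the log2 fold change divided by the square root of its F. There were 18 comparisons of 2 groups and 2 F tests of whether the 3 amputation responses differed between a glucose level and regular medium. CPM values use the same scaling.

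Also before the data were examined, 40 gene lists were fixed that cover inflammation, blood and tissue cell types, stress, metabolism, the cell cycle and the clock. Each was tested with camera on log2 CPM (prior count 2) with an estimated correlation between genes and adjusted over the lists of a comparison. Calls with a preset correlation of 0.01 are an alternative, and of the list tests of 2 groups those of cytokines at 24 h in regular medium (adjusted p = 0.014) and pancreatic enzymes at 48 h in 130 mM against regular medium (adjusted p = 0.015) held with the estimated correlation. Markers of cell types are also expressed by other tissues of the whole larva.

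Genes could be named when they were among the 8 largest rises or falls of a comparison, past the threshold with no overlap between the libraries of the groups, at a mean of at least 5 FPKM in the higher group and with a proper symbol; when they were list members past the threshold, up to 6 per list and comparison; or when they were among readouts fixed before the data were examined. For the F tests, the 8 smallest adjusted p-values took the place of the largest changes. Among these, genes whose call held without each single library and under the other tools and scalings, whose groups did not overlap, and in part those whose value moved by less than 1.5 times without any single library, were preferred as examples, a choice made after the data had been seen. Genes printed with a log2 change were thus chosen for groups that did not overlap. The exceptions were readouts that did not pass: mmp9 at 24 h in 130 mM, il1b, mmp9 and ins at 24 h in 222 mM, and il1b and mmp9 at 3 h in 222 mM.

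The labels do not say what a replicate number marks. Only for uncut larvae and 3 h in 222 mM did all same-number pairs correlate above 0.1 in their deviations from the group means (r = 0.174, 0.152 and 0.389 across genes), so the numbers were taken as pairs there and in no other comparison.

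The alternatives were another scaling (median ratios), no expression filter, limma on log2(FPKM + 0.1) or log2(FPKM + 1), DESeq2 1.42.0, the criterion in the series text, only the libraries compared, the replicate number as a block (over all groups, or on these 2 groups), each library left out in turn and the omission of 4 libraries apart. The code was tested on counts simulated for all 36 libraries from the mean of uncut regular medium, with changes put into uncut 130 mM. Of 67 genes changed 1.5-fold it recovered 14 (20.9%), of 67 changed 2-fold 51 (76.1%) and of 66 changed 4-fold 65 (98.5%), with 2 false genes among 132 called. A list of 32 members moved 2-fold was called and no other, which tests the code but not the power on real lists.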

Results

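Zebrafish larvae were kept for 14 days in regular medium, 130 mM or 222 mM glucose. RNA of whole larvae was sequenced uncut or 3, 24 or 48 h after caudal fin amputation. The series title places the work as a model of how diabetes affects inflammation and regeneration. The 12 groups held 3 libraries each. The first principal component of log2 CPM (counts scaled to the library size) held 21.3% of the variance and the second 16.7%. In 4 libraries the mean correlation with the other libraries of the group lay more than 0.02 below the correlation between those others: replicate 3 of uncut regular medium (0.9366 against 0.986), replicate 3 of uncut 222 mM (0.9545 against 0.9803), replicate 1 of regular medium at 3 h (0.9542 against 0.9845) and replicate 1 of 130 mM at 24 h (0.96 against 0.9816). All 36 libraries were kept, and each count of changed genes is followed by the count without these 4, an alternative chosen after the data had been seen. The labels do not say that replicates came from separate animals or pools of larvae, so the p-values measure only the spread between these samples, which may be technical. In what follows, "log2" before a value stands for the log2 fold change ± its standard error (3 libraries per group), p-values are adjusted over the 20120 genes tested, and a gene changed when its adjusted p lay under 0.05. Ranges over single libraries left out name the library behind the lowest value, then the highest. List members are counted where measured. Positions are on GRCz11.

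**Figure D1:**
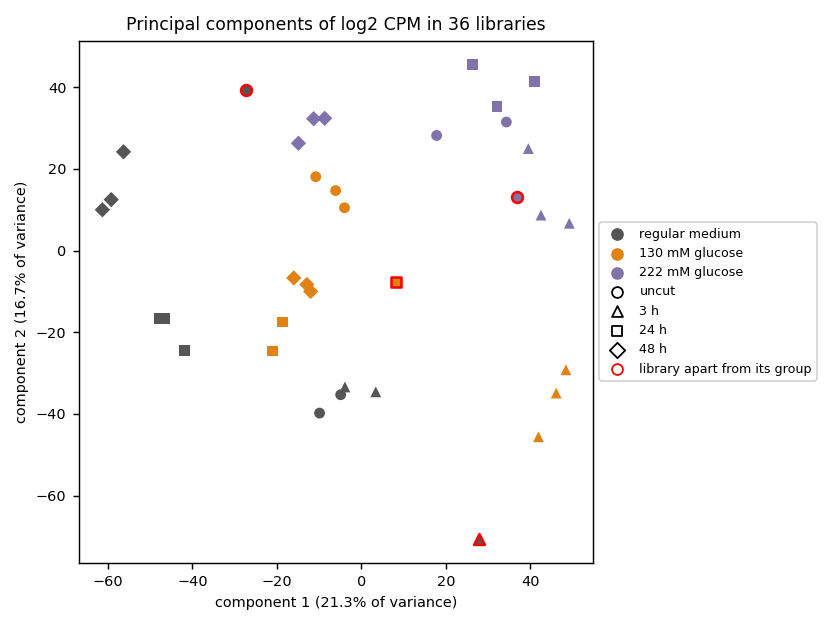
Principal components 1 (21.3% of variance) and 2 (16.7%) of log2 CPM, 1 point per library, coloured by medium and shaped by time after amputation; red rims mark the 4 libraries apart from their group. Replicate 3 of uncut regular medium lies at -27.3 and 39.4, while the other uncut regular-medium libraries lie at -9.9 and -39.8 and at -4.9 and -35.3.

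**Figure D2:**
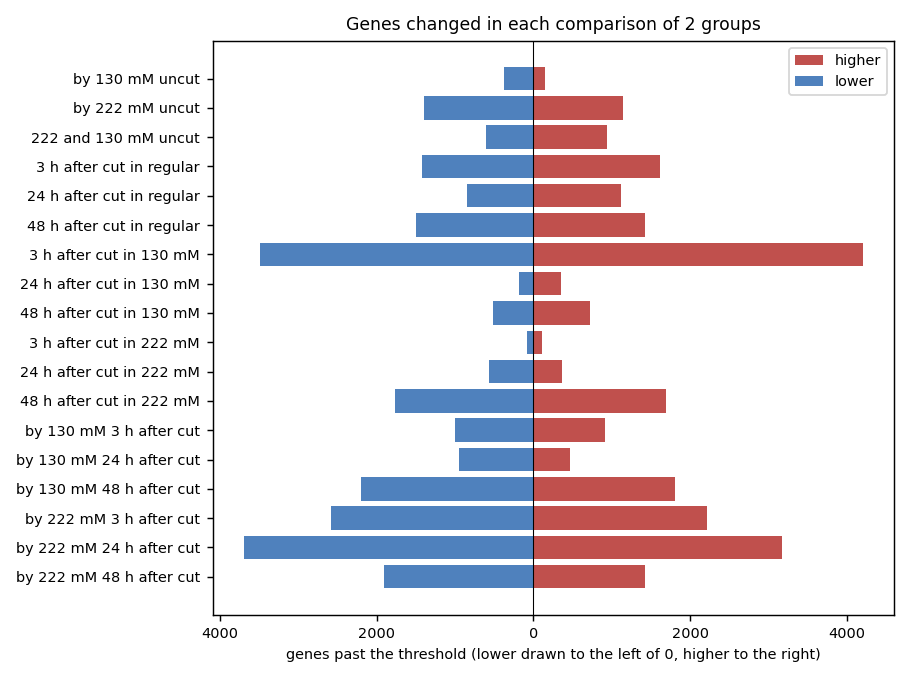
Genes past the threshold in each comparison of 2 groups, with higher genes drawn to the right of 0 and lower genes to the left. The longest pair of bars belongs to 3 h after amputation in 130 mM glucose (7692 genes) and the shortest to 3 h after amputation in 222 mM glucose (180 genes).

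The first question was what 130 mM glucose alone did to uncut larvae. The calcium channel gene trpv6 (ENSDARG00000014496, chromosome 16, 12294284 to 12319822) rose from 17.7 ± 0.448 to 97.7 ± 16.3 CPM (mean ± SD, n = 3), log2 2.47 ± 0.22, adjusted p = 4e-08. Ferritin-like fthl29 (log2 4.56 ± 0.54), the small heat shock protein gene hspb6 (log2 1.76 ± 0.33) and the ubiquitin-like modifier isg15 (log2 3.65 ± 0.68) also rose. Insulin (ins, ENSDARG00000035350, chromosome 5, 37854685 to 37857696) fell from 19.6 ± 5.16 to 6.07 ± 1.51 CPM, log2 -1.69 ± 0.27, adjusted p = 0.00097, and so did miox (log2 -2.19 ± 0.34), which encodes the inositol-degrading oxygenase, and stc1l (log2 -2.69 ± 0.51), a stanniocalcin. Among interferon response genes, 12 of 35 members rose and 23 did not pass. There were 16 rising adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Of the hepatocyte markers, 10 of 39 members fell and 29 did not pass. The number was 27 falling adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Of the enterocyte markers, 8 of 42 members fell and 34 did not pass, with falls of chia.3 (log2 -1.34 ± 0.19) and mep1b (log2 -1.3 ± 0.23), a chitinase and a meprin. This became 1 rising and 21 falling adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). For isg15 log2 was 4.29 without replicate 3 of uncut regular medium and 3.02 without replicate 2 of uncut 130 mM.

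In all, 529 genes changed, 153 higher and 376 lower in 130 mM glucose (edgeR quasi-likelihood test), and 5789 changed without the 4 libraries apart. This count was 115, 104 and 3635 without replicates 1, 2 and 3 of uncut regular medium and 236, 133 and 97 without replicates 1, 2 and 3 of uncut 130 mM. When single libraries were left out, the number of changed members ran from 2 to 13 for interferon response (without replicates 2 and 1 of uncut 130 mM) and from 1 to 32 for hepatocyte markers and from 2 to 27 for enterocyte markers (without replicates 1 and 3 of uncut regular medium). With only these 6 libraries 21 were called, no longer isg15, ins, miox and stc1l.

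The same question was put for 222 mM glucose. Rises included the muscle stress gene ankrd1a (log2 4.13 ± 0.72), the titin-capping tcap (log2 3.82 ± 0.53) and the small heat shock protein genes hspb9 (log2 3.64 ± 0.59; ENSDARG00000078674, chromosome 3, 33300522 to 33301321), hspb6 (log2 3.63 ± 0.35) and hspb11 (log2 3.49 ± 0.57). The aryl hydrocarbon receptor target cyp1a (log2 3.02 ± 0.55), the cytokine il11a (log2 4.67 ± 0.92), the matrix metalloproteinase mmp9 (log2 2.16 ± 0.43) and the cytokine-signalling suppressor socs3b (log2 1.48 ± 0.19) rose. Insulin (ins) fell (log2 -1.14 ± 0.26, adjusted p = 0.0041), and the thioredoxin-interacting txnipa (log2 0.85 ± 0.2, adjusted p = 0.0042) rose. Of the cholesterol synthesis genes, 2 of 32 members rose, 15 fell and 15 did not pass, with cyp51 (log2 -2.26 ± 0.44), fdps (log2 -2.26 ± 0.42) and sc5d (log2 -2.21 ± 0.41) among the falls. There were 2 rising and 19 falling adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Of the complement and acute-phase genes, 12 of 37 members rose, 1 fell and 24 did not pass, with c4b (log2 2.64 ± 0.38), cfb (log2 2 ± 0.39) and c7b (log2 1.98 ± 0.35). The number was 20 rising and 2 falling adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Of the cell cycle genes, 27 of 77 members fell and 50 did not pass. This became 50 falling adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Without replicate 3 of uncut 222 mM, log2 was 2.19 for ankrd1a, 3.13 for tcap, 2.35 for hspb9 and 2.07 for hspb11.

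The test called 2534 genes, 1144 higher and 1390 lower, and 5862 without the 4 libraries apart. Of the genes called with all libraries 45.1% were higher, against 21% of those called by limma on log2(FPKM + 0.1), where the median of all genes shifted by log2 -0.13. The count was 1471, 1482 and 4232 without replicates 1, 2 and 3 of uncut regular medium and 1643 without replicate 1 of uncut 222 mM. With 1 library left out, changed members numbered from 5 to 15 for complement and acute-phase genes (without replicates 3 and 2 of uncut 222 mM) and from 6 to 56 for cell cycle (without replicates 1 and 3 of uncut regular medium). From these 6 libraries alone 22 were called, of the genes given only tcap, hspb6 and il11a.

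Set directly against 130 mM, most complement and acute-phase genes were higher in uncut larvae in 222 mM glucose. Of this list, 25 of 37 members were higher and 12 did not pass. There were 32 higher and 1 lower adjusted over the list alone (adjusted p = 0.1 with an estimated correlation). Complement c3a.3 (log2 2.43 ± 0.48), cfh (log2 2.38 ± 0.44) and c4b (log2 2.31 ± 0.38) and the copper carrier cp (log2 2.29 ± 0.4) were higher. The clotting genes f5 (log2 2.27 ± 0.35), fgb (log2 2.06 ± 0.41) and fga (log2 2.02 ± 0.4) were higher too. Heat shock genes hspb9 (log2 3.54 ± 0.58) and hspb11 (log2 2.98 ± 0.56) were higher, in a list where 11 of 39 members were higher and 28 did not pass. The number was 20 higher adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). So were ankrd1a (log2 4.45 ± 0.74), tcap (log2 2.95 ± 0.51), fibronectin fn1b (log2 1.93 ± 0.32) and the AP-1 gene junbb (log2 1.35 ± 0.3). Of the unfolded-protein and amino acid response genes, 13 of 47 members were higher and 34 did not pass, with dnajb9b (log2 1.96 ± 0.37). This became 23 higher and 1 lower adjusted over the list alone (adjusted p = 0.1 with an estimated correlation). Lower at the higher dose were s100a11 (log2 -2.62 ± 0.32), the interferon-induced ifi46 (log2 -1.72 ± 0.28) and the chemokine ccl19b (log2 -1.71 ± 0.27). Without replicate 3 of uncut 222 mM, log2 was 2.25 for hspb9, 1.56 for hspb11, 2.52 for ankrd1a and 2.26 for tcap.

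The 2 doses differed in 1535 genes, 935 higher and 600 lower in 222 mM, and in 2721 without the libraries apart. Of those called with all libraries 60.9% were higher, against 28.6% of those called by limma on log2(FPKM + 0.1), where the median of all genes shifted by log2 -0.13. Counts of 952, 703 and 657 without replicates 1, 2 and 3 of uncut 130 mM and 905 without replicate 3 of uncut 222 mM were found. Over the single libraries left out, list members that differed ranged from 15 to 26 for complement and acute-phase genes (without replicate 3 of uncut 222 mM and replicate 1 of uncut 130 mM), from 4 to 13 for heat shock and chaperones (without replicates 3 and 2 of uncut 222 mM) and from 5 to 15 for the unfolded-protein and amino acid response (without replicate 2 of uncut 130 mM and replicate 2 of uncut 222 mM). In a fit of these 6 libraries 733 were called, no longer hspb9, hspb11 and ankrd1a.

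In regular medium, part of the interferon response and cell cycle lists rose in the first hours after amputation. Of the interferon response genes, 17 of 35 members rose and 18 did not pass, with mxe (log2 5.19 ± 0.78; ENSDARG00000014427, chromosome 9, 32824639 to 32837860) and isg15 (log2 4.05 ± 0.69). There were 18 rising and 1 falling adjusted over the list alone (adjusted p = 0.37 with an estimated correlation). Of the cell cycle genes, 34 of 77 members rose and 43 did not pass, including the mitotic kinase plk1 (log2 1.96 ± 0.21), the cyclin ccnb1 (log2 2.03 ± 0.29) and prc1a (log2 2.28 ± 0.3). The number was 43 rising adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). Of the fatty acid oxidation genes, 19 of 37 members rose and 18 did not pass, with cpt1b (log2 1.69 ± 0.22), the fatty acid carrier enzyme of mitochondria. This became 22 rising and 1 falling adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). Among oxidative stress genes, 22 of 49 members rose, 1 fell and 26 did not pass, with prdx1 (log2 1.52 ± 0.22) and gstp1.2 (log2 1.49 ± 0.18). There were 26 rising and 1 falling adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). The epidermal factor grhl3 (log2 1.11 ± 0.17) rose, and the clock repressor nr1d4b (log2 -2.48 ± 0.62) fell. The interleukin il1b (log2 1.34 ± 0.57, adjusted p = 0.11) did not pass (log2 0.71 without replicate 1 at 3 h). Without replicate 2 of uncut regular medium, log2 was 5.99 for mxe. Without replicate 3 it was 4.6 for mxe and 4.7 for isg15.

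Changed genes numbered 3038, 1617 higher and 1421 lower 3 h after the amputation, and 4536 without the libraries apart. The number was 1990 without replicate 3 of uncut regular medium and 2006 without replicate 2 of regular medium at 3 h. Changed members with 1 library left out ran from 10 to 18 for fatty acid oxidation (without replicate 3 of uncut regular medium and replicate 3 of regular medium at 3 h). With only these 6 libraries 3 were called, none of the genes given.

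By 24 h in regular medium, cytokine genes were higher as a list. Chemokines ccl20a.3 (log2 2.19 ± 0.43; ENSDARG00000101040, chromosome 2, 45191049 to 45193014) and ccl19b (log2 2.24 ± 0.27) and the tumour necrosis factor tnfb (log2 1.55 ± 0.29) rose among cytokine genes, where 6 of 24 members rose and 18 did not pass. The number was 10 rising adjusted over the list alone (adjusted p = 0.014 with an estimated correlation). Nitric oxide synthase nos2a (log2 3.26 ± 0.68) rose too. Interferon-regulatory factor irf1b (ENSDARG00000043249, chromosome 21, 45626136 to 45633317) went from 22.2 ± 3.89 to 116 ± 5.55 CPM, log2 2.39 ± 0.28, adjusted p = 6.9e-06, and the immunoproteasome subunit psmb9a (log2 2.25 ± 0.44) rose, in a list where 15 of 35 members rose and 20 did not pass. This became 23 rising and 1 falling adjusted over the list alone (adjusted p = 0.075 with an estimated correlation). Of the macrophage markers, 12 of 32 members rose and 20 did not pass, with perforin-like mpeg1 ENSDARG00000043093 (log2 1.42 ± 0.31), granulin grn2 (log2 1.31 ± 0.23) and the cathepsin ctss2.2 (log2 1.31 ± 0.16). There were 15 rising adjusted over the list alone (adjusted p = 0.09 with an estimated correlation). Inflammatory signalling genes included noxo1a (log2 1.64 ± 0.23), nox1 (log2 0.95 ± 0.16), nfkb2 (log2 0.81 ± 0.13) and socs3b (log2 1.17 ± 0.19), and 11 of 33 members rose and 22 did not pass. The number was 12 rising and 1 falling adjusted over the list alone (adjusted p = 0.12 with an estimated correlation). Most cholesterol synthesis genes were lower: 19 of 32 members fell and 13 did not pass, with the rate-limiting reductase hmgcra (log2 -1.85 ± 0.34, adjusted p = 0.0014). This became 23 falling adjusted over the list alone (adjusted p = 0.23 with an estimated correlation). Without replicate 3 of uncut regular medium, log2 was 2.82 for ccl20a.3, 4.3 for nos2a and 2.19 for mpeg1 ENSDARG00000043093.

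At this time 1968 genes had changed, 1115 upward and 853 downward, or 5423 without the libraries apart. The tally was 1242, 957 and 3359 without replicates 1, 2 and 3 of uncut regular medium and 679, 1189 and 894 without replicates 1, 2 and 3 of regular medium at 24 h. Left-out libraries moved the list members from 9 to 14 for interferon response (without replicate 1 of regular medium at 24 h and replicate 3 of uncut regular medium) and from 8 to 24 for cholesterol synthesis (without replicates 2 and 3 of uncut regular medium). From these 6 libraries alone 355 were called, no longer mpeg1 and hmgcra.

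At 48 h in regular medium, most cholesterol synthesis genes were again lower than in uncut larvae. Of this list, 23 of 32 members fell and 9 did not pass, and lss (log2 -4.19 ± 0.58) and hmgcra (log2 -2.5 ± 0.35) were among the falls. There were 24 falling adjusted over the list alone (adjusted p = 0.16 with an estimated correlation). Of the pancreatic digestive enzymes, 23 of 32 members fell and 9 did not pass, with trypsinogen prss1 (log2 -0.95 ± 0.16, adjusted p = 0.00017), cpa1 (log2 -1.21 ± 0.18) and cpa4 (log2 -1.21 ± 0.21, adjusted p = 0.00039; ENSDARG00000043722, chromosome 25, 16582172 to 16589461). The number was 23 falling adjusted over the list alone (adjusted p = 0.16 with an estimated correlation). Rises included the receptor kinase grk5 (ENSDARG00000032801, chromosome 10, 2715548 to 2755378), which went from 8.74 ± 1.53 to 57.6 ± 4.74 CPM, log2 2.72 ± 0.16, adjusted p = 9e-13, and irf1a (log2 2.64 ± 0.5). Of the skeletal muscle genes, 27 of 74 members rose, 1 fell and 46 did not pass, with myosin myha (log2 1.68 ± 0.24) and titin ttn ENSDARG00000000563 (log2 1.56 ± 0.22). This became 30 rising and 2 falling adjusted over the list alone (adjusted p = 0.23 with an estimated correlation).

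The comparison called 2925 genes, of which 1426 were higher and 1499 lower than in uncut larvae, and 7594 without the libraries apart. Its size was 1176, 976 and 5720 without replicates 1, 2 and 3 of uncut regular medium and 1721, 1774 and 1368 without replicates 1, 2 and 3 of regular medium at 48 h. In a fit of these 6 libraries 644 were called, no longer hmgcra.

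In 130 mM glucose, amputation was followed at 3 h by a change of 7692 of the 20120 genes tested. Rises included the AP-1 factors fosl1a (log2 4.09 ± 0.91, adjusted p = 0.0012; ENSDARG00000015355, chromosome 14, 30739476 to 30747686) and atf3 (log2 2.13 ± 0.55), interleukin il1b (log2 3.12 ± 0.59, adjusted p = 0.00027), chemokine cxcl8a (log2 1.38 ± 0.42) and mmp9 (log2 1.69 ± 0.42). Of the immediate early genes, 13 of 39 members rose, 1 fell and 25 did not pass. There were 13 rising and 1 falling adjusted over the list alone (adjusted p = 0.68 with an estimated correlation). In the list of fin wound epidermis and blastema, 16 of 61 members rose, 5 fell and 40 did not pass (16 rising and 5 falling adjusted over the list alone, adjusted p = 0.79 with an estimated correlation, median log2 0.03, which flips to -0.03 on log2(FPKM + 0.1)). Insulin (ins) went from 6.07 ± 1.51 to 14.6 ± 2.97 CPM, log2 1.27 ± 0.27, adjusted p = 0.00055. Of the cell cycle genes, 73 of 77 members rose and 4 did not pass, with the replication genes mcm2 (log2 2.24 ± 0.42) and gins2 (log2 2.4 ± 0.64) and pcna (log2 1.32 ± 0.29). The number was 73 rising adjusted over the list alone (adjusted p = 0.21 with an estimated correlation). Of the cholesterol synthesis genes, 30 of 32 members rose and 2 did not pass, with hmgcs1 (log2 3.27 ± 0.58) and sqlea (log2 2.91 ± 0.72), and the desaturase scd (log2 2.64 ± 0.45) rose too. This became 30 rising adjusted over the list alone (adjusted p = 0.21 with an estimated correlation). Of the proteasome genes, 36 of 44 members rose and 8 did not pass, with psmb5 (log2 1.24 ± 0.18). There were 36 rising adjusted over the list alone (adjusted p = 0.51 with an estimated correlation). In the unfolded-protein and amino acid response, 34 of 47 members rose, 1 fell and 12 did not pass, with asparagine synthetase asns (log2 2.12 ± 0.28) and dnajb9b (log2 2.31 ± 0.37). The number was 36 rising and 2 falling adjusted over the list alone (adjusted p = 0.18 with an estimated correlation). The synaptic gene snap25b (log2 -0.77 ± 0.14) fell, as did mpeg1 ENSDARG00000043093 (log2 -1.5 ± 0.31, adjusted p = 0.00058).

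This was the largest of the 18 comparisons, with 7692 genes, 4206 higher and 3486 lower, and 9824 without the libraries apart. No single library left out moved the count by over 1.5 times. List members with 1 library left out lay from 10 to 16 for fin wound genes (without replicates 1 and 2 of 130 mM at 3 h).

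By 24 h in 130 mM glucose 538 genes differed from the uncut larvae of the same medium. The calcium channel transcript trpv6 fell to 15.4 ± 2.58 CPM, log2 -2.66 ± 0.22, adjusted p = 7.4e-09, with ferritin-like fthl29 (log2 -3.45 ± 0.51) and s100a11 (log2 -2.29 ± 0.32). In the interferon response list, 1 of 35 members rose, 7 fell and 27 did not pass. This became 4 rising and 17 falling adjusted over the list alone (adjusted p = 0.59 with an estimated correlation). Rises included the apolipoprotein apoc1 (log2 1.82 ± 0.32) and vitronectin vtna (log2 1.65 ± 0.29). Of the hepatocyte markers, 22 of 39 members rose and 17 did not pass. There were 31 rising adjusted over the list alone (adjusted p = 0.56 with an estimated correlation). Interleukin il1b (log2 0.68 ± 0.58, adjusted p = 0.53) and mmp9 (log2 0.19 ± 0.42, adjusted p = 0.83) did not pass.

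The 538 genes were 357 higher and 181 lower, against 3744 without the libraries apart, which include replicate 1 at 24 h. This number was 312, 78 and 92 without replicates 1, 2 and 3 of uncut 130 mM and 1215, 126 and 81 without replicates 1, 2 and 3 of 130 mM at 24 h. Members changed with 1 library left out numbered from 1 to 10 for interferon response (without replicates 2 and 1 of uncut 130 mM) and from 1 to 26 for hepatocyte markers (without replicate 2 of uncut 130 mM and replicate 1 of 130 mM at 24 h). From these 6 libraries alone apoc1 was no longer called.

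At 48 h in 130 mM glucose, part of the skeletal muscle and keratinocyte lists was higher than in uncut larvae of that medium. Of the skeletal muscle genes, 34 of 74 members rose and 40 did not pass, with actin acta1a (log2 1.96 ± 0.23) and mybpc2b (log2 1.41 ± 0.23). The number was 52 rising and 2 falling adjusted over the list alone (adjusted p = 0.081 with an estimated correlation). Of the keratinocyte markers, 19 of 49 members rose, 1 fell and 29 did not pass, with krt15 (log2 1.26 ± 0.2), krt94 (log2 1.1 ± 0.19) and elf3 (log2 1.04 ± 0.22). This became 20 rising and 2 falling adjusted over the list alone (adjusted p = 0.21 with an estimated correlation). Of the lens crystallins, 9 of 54 members rose and 45 did not pass, with cryaa (log2 3.12 ± 0.55), cryba1a (log2 3.18 ± 0.54) and crygmx (log2 2.68 ± 0.58). There were 22 rising adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Myeloperoxidase mpx (log2 1.58 ± 0.34, adjusted p = 0.0079) of neutrophils rose. Glycogen synthase gys1 (log2 0.7 ± 0.11) rose and the gluconeogenic pck1 (log2 -1.27 ± 0.29, adjusted p = 0.01) fell, and the glucose transporter slc2a2 (log2 1.12 ± 0.22) rose. Falls included cyp1a (log2 -2.64 ± 0.54), ferritin-like fthl29 (log2 -3.1 ± 0.5) and trpv6 (log2 -1.13 ± 0.21).

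Past the threshold were 1236 genes, 720 higher and 516 lower, and 4148 without the libraries apart. With all libraries 58.3% were higher, against 28.9% of those called by limma on log2(FPKM + 0.1), where the median of all genes shifted by log2 -0.133. The figure was 663, 299 and 335 without replicates 1, 2 and 3 of uncut 130 mM and 605, 326 and 332 without replicates 1, 2 and 3 of 130 mM at 48 h. The changed members with 1 library out ranged from 19 to 25 for muscle (without replicates 2 and 1 of 130 mM at 48 h), from 9 to 12 for keratinocyte markers (without replicates 2 and 1 of uncut 130 mM) and from 3 to 6 for lens crystallins (without replicate 3 of uncut 130 mM and replicate 1 of 130 mM at 48 h). In a fit of these 6 libraries 6667 were called.

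In 222 mM glucose, few transcripts were told apart 3 h after amputation. The desmosome gene dspa (log2 0.88 ± 0.16), the ionocyte potassium channel kcnj1a ENSDARG00000090866 (log2 1.25 ± 0.19) and the cone transducin gnat2 (log2 0.84 ± 0.13) rose, and the transcription factor foxq1a (log2 -1.39 ± 0.24) fell. The chemokine cxcl8a (log2 2.11 ± 0.41, adjusted p = 0.011) rose in the full data, a call lost without replicate 1 or 2 of the uncut group or replicate 1 at 3 h (log2 2.01, 1.99 and 1.67). Of the cytokine genes, 5 of 24 members rose and 19 did not pass. The number was 6 rising adjusted over the list alone (adjusted p = 0.22 with an estimated correlation). Interleukin il1b (log2 1.51 ± 0.55, adjusted p = 0.19) and mmp9 (log2 1.08 ± 0.41, adjusted p = 0.22) did not pass, though without replicate 3 of uncut 222 mM both did (log2 2.22 and 1.64), and without replicate 1 at 3 h il1b was at log2 0.74.

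The test called 180 genes (103 higher, 77 lower) from 2864 at an unadjusted p under 0.05, and 3598 without the libraries apart, which include replicate 3 of the uncut group. With single libraries left out it called 42, 17 and 1214 without replicates 1, 2 and 3 of uncut 222 mM and 36 and 567 without replicates 2 and 3 of 222 mM at 3 h. The changed members then numbered from 0 (edgeR quasi-likelihood test, 7 at an unadjusted p under 0.05) to 5 for cytokines (without replicates 2 and 3 of uncut 222 mM). The same-numbered libraries of these groups deviated together, and the replicate number as a block gave 312 genes (163 higher, 149 lower; 178 shared with the 180), or 26 of 2202 at an unadjusted p under 0.05 with only these 6 libraries, against 0 of 1284 there without it.

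At 24 h in 222 mM glucose, part of the skeletal muscle list was lower than in uncut larvae. Of the skeletal muscle genes, 12 of 74 members fell and 62 did not pass, with myosin myha (log2 -1.74 ± 0.24), actin acta1a (log2 -1.55 ± 0.23) and myl1 (log2 -1.54 ± 0.25). This became 23 falling adjusted over the list alone (adjusted p = 0.66 with an estimated correlation). Of the matrix genes, 6 of 68 members fell and 62 did not pass, among them matrilin matn1 (log2 -2.39 ± 0.44). There were 15 falling adjusted over the list alone (adjusted p = 0.92 with an estimated correlation). The aryl hydrocarbon receptor target cyp1a (log2 -3.57 ± 0.57), its repressor ahrra (log2 -2.24 ± 0.32), the growth factor fgf7 (log2 -2.51 ± 0.43) and foxq1a (log2 -2.05 ± 0.25) fell. Rises included eevs (log2 2.87 ± 0.46), of sunscreen compound synthesis, the deubiquitinase usp21 (log2 1.81 ± 0.36), the cone kinase grk7a (log2 1.58 ± 0.3) and the glutamate transporter slc1a2a (log2 1.47 ± 0.33). Interleukin il1b (log2 0.2 ± 0.54, adjusted p = 0.89), mmp9 (log2 0.58 ± 0.41, adjusted p = 0.48) and ins (log2 -0.08 ± 0.26, adjusted p = 0.92) did not pass. Without replicates 3 and 1 of uncut 222 mM il1b was at log2 0.91 and -0.13, and without replicate 2 at 24 h at -0.02, while ins was at log2 0.16 and 0.03 without replicate 1 of the uncut or the 24 h group.

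There were 926 such genes, 365 higher and 561 lower, and 3625 without the libraries apart. With all libraries in, 39.4% were higher, against 67.9% of those called by limma on log2(FPKM + 0.1). The number became 529, 562 and 1660 without replicates 1, 2 and 3 of uncut 222 mM and 457, 609 and 542 without replicates 1, 2 and 3 of 222 mM at 24 h. With 1 library missing, the members changed ran from 2 to 12 for extracellular matrix (without replicate 1 of 222 mM at 24 h and replicate 3 of uncut 222 mM). From these 6 libraries alone 225 were called.

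After 48 h in 222 mM glucose, falls included members of the glucocorticoid-responsive and clock lists. Of the glucocorticoid-responsive genes, 10 of 26 members fell and 16 did not pass, with fkbp5 (log2 -3.42 ± 0.63), klf9 (log2 -2.83 ± 0.64) and pck1 (log2 -2.25 ± 0.3, adjusted p = 9.1e-06). The number was 13 falling adjusted over the list alone (adjusted p = 0.33 with an estimated correlation). Of the clock genes, 5 of 41 members rose, 13 fell and 23 did not pass, with nfil3-5 (log2 -4.6 ± 0.64), rorcb (log2 -2.86 ± 0.31) and clocka (log2 -2.05 ± 0.28) among the falls. This became 8 rising and 14 falling adjusted over the list alone (adjusted p = 0.7 with an estimated correlation). The detoxification gene cyp1a (ENSDARG00000098315, chromosome 18, 5588068 to 5598958) went from 4540 ± 789 to 179 ± 10.6 CPM, log2 -4.67 ± 0.6, adjusted p = 1e-05. Of the pancreatic enzymes, 14 of 32 members fell and 18 did not pass, with cpa1 (log2 -1.18 ± 0.18) and prss1 (log2 -0.57 ± 0.15, adjusted p = 0.01). There were 16 falling adjusted over the list alone (adjusted p = 0.7 with an estimated correlation). The metalloproteinase mmp9 (log2 -1.81 ± 0.43, adjusted p = 0.0045), the AP-1 gene junbb (log2 -1.24 ± 0.3) and trpv6 (log2 -1.48 ± 0.21) fell. Rises included the glucose transporter slc2a1a (log2 2.49 ± 0.32), the Mx gene mxc (log2 2.49 ± 0.36), plekhs1.1 (log2 3.84 ± 0.55), oxgr1a ENSDARG00000033684 (log2 3.59 ± 0.41) and mpeg1 ENSDARG00000043093 (log2 1.96 ± 0.31, adjusted p = 0.00011). The other copy, mpeg1 ENSDARG00000055290, moved little, from 11.8 to 13.7 CPM in the uncut libraries to 14.6 to 15.4 at 48 h. The chemokine ccl19b (log2 2.1 ± 0.28) rose in a list where 7 of 24 members rose and 17 did not pass. The number was 7 rising and 1 falling adjusted over the list alone (adjusted p = 0.25 with an estimated correlation).

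Compared with uncut larvae in that medium, 3451 genes differed, 1692 higher and 1759 lower, and 4961 without the libraries apart. Among calls with all libraries 49% were higher, against 73.6% of those called by limma on log2(FPKM + 0.1), where the median of all genes shifted by log2 0.116. Counts were 2167 without replicate 1 of uncut 222 mM and 2191 and 2104 without replicates 1 and 3 of 222 mM at 48 h. Members past the threshold with 1 library out ran from 4 to 7 for cytokines (without replicates 1 and 3 of uncut 222 mM).

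**Figure D3:**
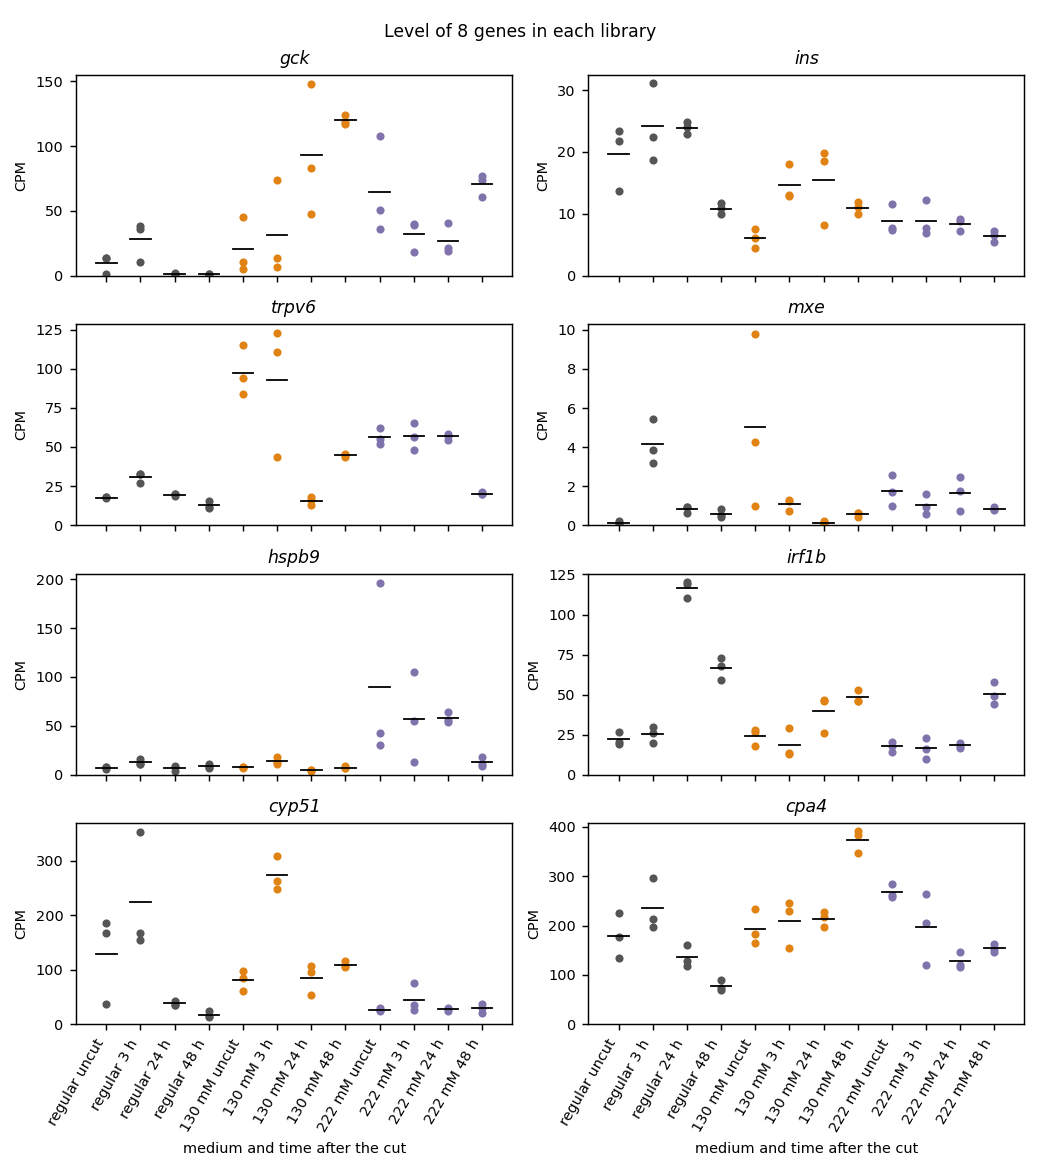
CPM of 8 genes in each library (points) and the group mean (bars), ordered by medium and time after amputation. Mean gck CPM in 130 mM glucose at 48 h was 120 ± 3.46, against 1.01 ± 0.427 in regular medium.

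The amputated groups were also compared between media at each time. At 3 h, the desaturase gene scd (log2 2.51 ± 0.45), fatty acid synthase fasn (log2 0.75 ± 0.16, adjusted p = 0.0032) and gpam (log2 0.76 ± 0.13) were higher in 130 mM glucose than in regular medium, in a list where 8 of 45 members were higher, 1 was lower and 36 did not pass. This became 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.58 with an estimated correlation). Amino acid response genes asns (log2 1.3 ± 0.28) and sesn2 (log2 1.19 ± 0.22) were higher. Of the interferon response genes, 14 of 35 members were lower and 21 did not pass. There were 17 lower adjusted over the list alone (adjusted p = 0.58 with an estimated correlation). The keratins krt15 (log2 -1.03 ± 0.2) and cyt1 (log2 -0.65 ± 0.14) and the hypoxia-responsive carbonic anhydrase ca9 (log2 -1.76 ± 0.31) were lower. Of the clock genes, 8 of 41 members were higher, 1 was lower and 32 did not pass. The number was 12 higher and 2 lower adjusted over the list alone (adjusted p = 0.58 with an estimated correlation). Insulin (ins, log2 -0.72 ± 0.26, adjusted p = 0.074) and il1b (log2 1.58 ± 0.55, adjusted p = 0.067) did not pass. DESeq2 called both, limma on FPKM called il1b, and il1b also passed without replicate 1 of regular medium at 3 h (log2 2.21).

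Between these groups 1911 genes differed, 913 higher and 998 lower in 130 mM glucose, and 6405 without the libraries apart, which include replicate 1 of regular medium at 3 h. It was 4247, 382 and 515 without replicates 1, 2 and 3 of regular medium at 3 h and 1026, 871 and 1071 without replicates 1, 2 and 3 of 130 mM at 3 h. Members that differed with 1 library left out numbered from 4 to 11 for fatty acid synthesis and from 1 to 23 for circadian clock (without replicates 2 and 1 of regular medium at 3 h) and from 1 to 17 for interferon response (without replicates 3 and 1 of regular medium at 3 h). With only these 6 libraries 0 of 4286 at an unadjusted p under 0.05 (edgeR; DESeq2 on all libraries 2434) were called.

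At 24 h, part of the cytokine and inflammatory signalling lists was lower in 130 mM glucose than in regular medium. Of the cytokine genes, 5 of 24 members were lower and 19 did not pass, with ccl20a.3 (log2 -2.37 ± 0.43), ccl19b (log2 -1.9 ± 0.27) and tnfb (log2 -1.89 ± 0.3). This became 5 lower adjusted over the list alone (adjusted p = 0.21 with an estimated correlation). In inflammatory signalling, 10 of 33 members were lower and 23 did not pass, with nox1 (log2 -1.05 ± 0.16), nfkb2 (log2 -0.87 ± 0.13) and socs3b (log2 -1.05 ± 0.19, adjusted p = 0.0011). There were 12 lower adjusted over the list alone (adjusted p = 0.21 with an estimated correlation). Of the interferon response genes, 9 of 35 members were lower and 26 did not pass, with irf1b (log2 -1.56 ± 0.27) and psmb9a (log2 -1.92 ± 0.43). The number was 18 lower adjusted over the list alone (adjusted p = 0.21 with an estimated correlation). Glucokinase, gck (ENSDARG00000068006, chromosome 8, 40476811 to 40490593), the liver enzyme that phosphorylates glucose, was higher, at 92.9 ± 50.8 against 1.57 ± 0.542 CPM, log2 5.88 ± 1.02, adjusted p = 0.0011. In glycolysis, 6 of 43 members were higher and 37 did not pass, with pklr (log2 1.5 ± 0.31). This became 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.71 with an estimated correlation). The insulin-like growth factor binding igfbp1b (log2 -3.37 ± 0.51) was lower.

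The count was 1415 genes, 471 higher and 944 lower in 130 mM glucose, and 2228 without the libraries apart. It came to 627, 752 and 660 without replicates 1, 2 and 3 of regular medium at 24 h and 509 without replicate 1 of 130 mM at 24 h. Those list members numbered from 3 to 5 for cytokines (without replicates 1 and 2 of regular medium at 24 h), from 3 to 10 for interferon response (without replicates 1 and 2 of 130 mM at 24 h) and from 3 to 5 for glycolysis (without replicates 2 and 1 of regular medium at 24 h).

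At 48 h, digestive enzymes of the pancreas differed between the media. In 130 mM glucose, 28 of 32 members were higher and 4 did not pass, the 1 list of this comparison past the threshold. There were 28 higher adjusted over the list alone (adjusted p = 0.015 with an estimated correlation). Carboxypeptidase cpa4 stood at 374 ± 23.9 against 77.4 ± 10.7 CPM, log2 2.27 ± 0.22, adjusted p = 5.6e-08, with prss1 (log2 1.43 ± 0.16, adjusted p = 3.4e-07), ela2 (log2 1.84 ± 0.22) and cel ENSDARG00000029822 (log2 1.88 ± 0.18). Glucokinase (gck) was higher (log2 6.9 ± 1.08, adjusted p = 9.9e-05). In glycolysis, 26 of 43 members were higher, 3 were lower and 14 did not pass, with pklr (log2 2.52 ± 0.32) and slc2a2 (log2 1.3 ± 0.22). The number was 26 higher and 3 lower adjusted over the list alone (adjusted p = 0.35 with an estimated correlation). Of the cholesterol synthesis genes, 19 of 32 members were higher and 13 did not pass, with sqlea (log2 3.45 ± 0.77), cyp51 (log2 2.64 ± 0.44, adjusted p = 2e-04; ENSDARG00000042641, chromosome 19, 598657 to 617246) and hmgcra (log2 2.48 ± 0.35, adjusted p = 2.6e-05). This became 23 higher and 3 lower adjusted over the list alone (adjusted p = 0.48 with an estimated correlation). The red cell genes alas2 (log2 2.09 ± 0.26) and hbbe2 (log2 1.4 ± 0.25) were higher. The muscle ubiquitin ligases trim63a (log2 -2.69 ± 0.58) and fbxo32 (log2 -2.4 ± 0.38) were lower, in a list where 8 of 74 members were higher, 17 were lower and 49 did not pass. There were 10 higher and 18 lower adjusted over the list alone (adjusted p = 0.83 with an estimated correlation). Lower as well were igfbp1b (log2 -2.43 ± 0.49) and the pyruvate dehydrogenase kinases pdk2b (log2 -1.99 ± 0.43) and pdk4 (log2 -1.35 ± 0.24).

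In this comparison 3999 genes differed, 1806 higher and 2193 lower in 130 mM glucose, and 6877 without the libraries apart. With every library kept, 45.2% were higher, against 22.5% of those called by limma on log2(FPKM + 0.1), where the median of all genes shifted by log2 -0.15. The result was 2617 and 2404 without replicates 1 and 3 of regular medium at 48 h and 2404 and 2614 without replicates 2 and 3 of 130 mM at 48 h. Leaving single libraries out moved the members from 15 to 21 for glycolysis (without replicates 3 and 2 of regular medium at 48 h), from 9 to 12 for cholesterol synthesis (without replicate 3 of regular medium at 48 h and replicate 1 of 130 mM at 48 h) and from 11 to 15 for muscle (without replicate 1 of 130 mM at 48 h and replicate 1 of regular medium at 48 h). In a fit of these 6 libraries 9264 were called.

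At 3 h, most cell cycle genes were lower in 222 mM glucose than in regular medium. Of the cell cycle genes, 60 of 77 members were lower and 17 did not pass, with ccnb1 (log2 -2.79 ± 0.3) and cdk1 (log2 -2.67 ± 0.38). The number was 65 lower adjusted over the list alone (adjusted p = 0.25 with an estimated correlation). Of the interferon response genes, 24 of 35 members were lower and 11 did not pass, with ifit15 (log2 -5.65 ± 1). This became 1 higher and 25 lower adjusted over the list alone (adjusted p = 0.28 with an estimated correlation). Higher in 222 mM were most immediate early genes, where 24 of 39 members were higher and 15 did not pass, with junbb (log2 1.44 ± 0.3, adjusted p = 0.0011). There were 28 higher and 1 lower adjusted over the list alone (adjusted p = 0.28 with an estimated correlation). Also higher were socs3b (log2 1.42 ± 0.19, adjusted p = 6.5e-06), mmp9 (log2 1.75 ± 0.42, adjusted p = 0.0041), hspb11 (log2 2.85 ± 0.56), the desaturase scd (log2 2.88 ± 0.46) and the sterol-esterifying soat2 (log2 2.71 ± 0.27). Of the clock genes, 19 of 41 members were higher and 22 did not pass. The number was 22 higher adjusted over the list alone (adjusted p = 0.44 with an estimated correlation). Insulin (ins) was lower (log2 -1.44 ± 0.27, adjusted p = 3e-04). Without replicate 1 of regular medium at 3 h, log2 was 2.14 for junbb.

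Altogether 4800 genes differed, 2213 higher and 2587 lower in 222 mM glucose, and 7064 without the libraries apart. Of the calls with all libraries 46.1% were higher, against 23.8% of those called by limma on log2(FPKM + 0.1), where the median of all genes shifted by log2 -0.129. No single library moved this count by over 1.5 times. With a library left out, members higher in 222 mM numbered from 12 to 34 for immediate early genes (without replicates 3 and 1 of regular medium at 3 h). For circadian clock they numbered from 6 to 26 (without replicate 2 of 222 mM at 3 h and replicate 1 of regular medium at 3 h). With only these 6 libraries 736 were called, no longer junbb, mmp9 and hspb11.

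At 24 h, many members of the macrophage, matrix, keratinocyte and muscle lists were lower in 222 mM glucose. Of the macrophage markers, 19 of 32 members were lower and 13 did not pass, with grn2 (log2 -2.63 ± 0.24) and mpeg1 ENSDARG00000055290 (log2 -1.7 ± 0.2, adjusted p = 1.4e-07). This became 1 higher and 20 lower adjusted over the list alone (adjusted p = 0.23 with an estimated correlation). Lysozyme lyz (log2 -1.48 ± 0.29, adjusted p = 0.00026), the T-cell kinase lck (log2 -3.13 ± 0.4, adjusted p = 6.2e-07; ENSDARG00000102525, chromosome 17, 25344734 to 25382376) and rag1 (log2 -2.46 ± 0.32) were lower. Of the interferon response genes, 1 of 35 members was higher, 18 were lower and 16 did not pass, with irf1b (log2 -2.67 ± 0.28). There were 2 higher and 20 lower adjusted over the list alone (adjusted p = 0.46 with an estimated correlation). Of the matrix genes, 2 of 68 members were higher, 40 were lower and 26 did not pass, with matn1 (log2 -3.21 ± 0.45) and col2a1a (log2 -2.88 ± 0.41). The number was 2 higher and 40 lower adjusted over the list alone (adjusted p = 0.56 with an estimated correlation). Of the keratinocyte markers, 2 of 49 members were higher, 26 were lower and 21 did not pass, with krtt1c19e (log2 -3.09 ± 0.54) and krt5 (log2 -1.74 ± 0.23). This became 2 higher and 27 lower adjusted over the list alone (adjusted p = 0.46 with an estimated correlation). Of the skeletal muscle genes, 5 of 74 members were higher, 34 were lower and 35 did not pass, with acta1b (log2 -3.77 ± 0.61) and pvalb1 (log2 -2.32 ± 0.27). There were 7 higher and 39 lower adjusted over the list alone (adjusted p = 0.56 with an estimated correlation). Higher were tcap (log2 4.14 ± 0.54), gck (log2 4.1 ± 0.95, adjusted p = 0.0017), scd (log2 3.53 ± 0.47), fasn (log2 1.2 ± 0.16, adjusted p = 9.6e-07), hspb6 (log2 3.25 ± 0.34) and hspb9 (log2 3.1 ± 0.57). Insulin (ins) was lower (log2 -1.51 ± 0.27, adjusted p = 6.8e-05).

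The groups differed in 6862 genes, 3166 higher and 3696 lower in 222 mM glucose, and in 9338 without the libraries apart. No count without a single library differed by over 1.5 times.

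At 48 h, gck was higher in 222 mM than in regular medium, 70.6 ± 8.7 against 1.01 ± 0.427 CPM, log2 6.13 ± 1.05, adjusted p = 0.00027. At 3 h the media overlapped (10.5 to 38 CPM in regular medium, 6.84 to 73.9 in 130 mM, 18.4 to 39.5 in 222 mM). In glycolysis, 15 of 43 members were higher and 28 did not pass, with pklr (log2 1.64 ± 0.31) and slc2a2 (log2 1.21 ± 0.22). The number was 17 higher and 2 lower adjusted over the list alone (adjusted p = 0.5 with an estimated correlation). Of the pancreatic enzymes, 19 of 32 members were higher and 13 did not pass, with cel ENSDARG00000017490 (log2 1.36 ± 0.17), amy2a (log2 1.24 ± 0.19) and prss1 (log2 0.91 ± 0.16, adjusted p = 0.00015). This became 23 higher adjusted over the list alone (adjusted p = 0.27 with an estimated correlation). Amino acid and folate enzymes asns (log2 1.6 ± 0.28) and mthfd2 (log2 2 ± 0.43) were higher. The gluconeogenic pck1 (log2 -1.75 ± 0.29, adjusted p = 0.00016), fbp1b (log2 -1.19 ± 0.17) and igfbp1b (log2 -2.68 ± 0.49) were lower, and hmgcra (log2 1.66 ± 0.34, adjusted p = 0.0014) and fasn (log2 0.66 ± 0.16, adjusted p = 0.0033) higher. Of the clock genes, 10 of 41 members were higher, 11 were lower and 20 did not pass, with nfil3-5 (log2 -3.55 ± 0.61) and rorcb (log2 -2.99 ± 0.32) lower and ciartb (log2 2.08 ± 0.46) higher. There were 17 higher and 12 lower adjusted over the list alone (adjusted p = 0.98 with an estimated correlation, median log2 0.16, mean log2 0.12 and test direction down).

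The last of these comparisons called 3325 genes, 1418 higher and 1907 lower in 222 mM glucose, and 5900 without the libraries apart. This came to 2142, 2114 and 2187 without replicates 1, 2 and 3 of regular medium at 48 h and 1880 and 2171 without replicates 1 and 3 of 222 mM at 48 h. Its list members with 1 library out ran from 8 to 14 for glycolysis (without replicate 3 of 222 mM at 48 h and replicate 2 of regular medium at 48 h). In a fit of these 6 libraries 8284 were called.

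**Figure D4:**
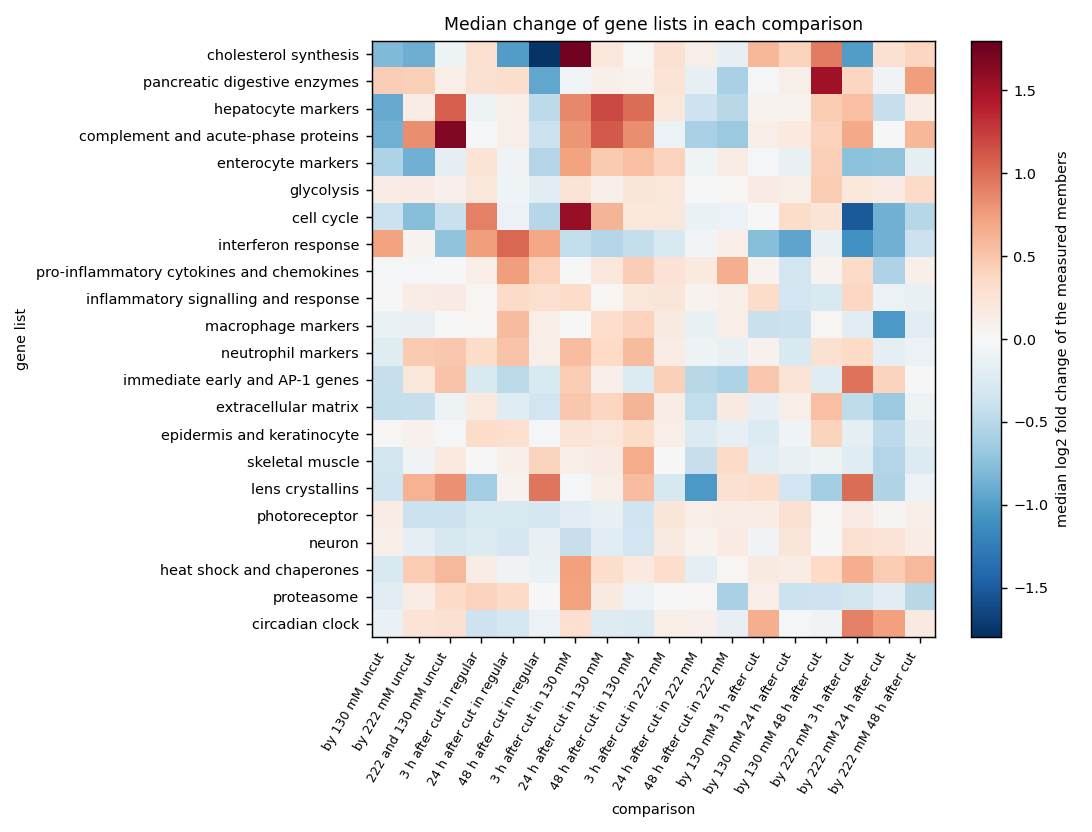
Median log2 fold change of 22 gene lists (vertical axis) in each comparison of 2 groups (horizontal axis), red for higher and blue for lower. Cholesterol synthesis had medians of -1.76 at 48 h in regular medium and 1.74 at 3 h in 130 mM glucose, and pancreatic enzymes 1.52 in 130 mM against regular medium at 48 h.

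Both glucose groups were compared with the same regular-medium libraries, so chance values are shared. In uncut larvae 72 genes were higher and 197 lower at both doses and 3 went opposite ways, where independent lists of those lengths would share 8.7 and 26. At 3 h the shared calls were 502 higher, 547 lower and 2 opposite (100.4 and 128.3 for independent lists), at 24 h 278, 618 and 15 (74.1 and 173.4), and at 48 h 622, 758 and 25 (127.3 and 207.9). Across genes, which are not independent replicates, the log2 changes at the 2 doses correlated with r = 0.51, 0.63, 0.52 and 0.56 in uncut larvae and at 3, 24 and 48 h. Data simulated 20 times, with all libraries redrawn gene by gene and both glucose groups unchanged, gave 0.49, 0.49, 0.5 and 0.49. The covariances were 0.16, 0.21, 0.21 and 0.19, above the simulated ones by 0.11, 0.17, 0.16 and 0.15. With 3 libraries the shared group cannot be split, and part of the excess may come from it.

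Whether changes from uncut larvae (responses) differed between media was tested over all 3 times. Between 130 mM glucose and regular medium 3605 genes differed (F test), 11179 without the libraries apart, and 2318 without replicate 2 of uncut regular medium, 7591 without replicate 3 of uncut regular medium and 5976 without replicate 1 of regular medium at 3 h. The response of the sterol enzyme hmgcra (adjusted p = 0.00055) was log2 3.24 ± 0.48 higher in 130 mM at 48 h, that of trypsinogen prss1 (adjusted p = 0.00024) log2 1.01 ± 0.22 higher and that of glucokinase gck (adjusted p = 0.0013) log2 5.8 ± 1.28 higher (log2 7.23 without replicate 1 of uncut 130 mM). That of tnfb (adjusted p = 0.0021) was lower at 24 h (log2 -1.87 ± 0.42). Of the cholesterol synthesis genes, 21 of 32 members were higher and 11 did not pass in their response at 48 h. The number was 24 higher and 1 lower adjusted over the list alone (adjusted p = 0.31 with an estimated correlation). Members higher numbered 14 and 13 without replicates 1 and 2 of uncut regular medium, and without replicate 3 the list passed (adjusted p = 0.036). Of the interferon response genes, 18 of 35 members were lower and 17 did not pass at 24 h, the 1 list past the threshold in these differences. This became 21 lower adjusted over the list alone (adjusted p = 0.033 with an estimated correlation). That call was lost without replicate 3 of uncut regular medium (adjusted p = 0.23), replicate 2 of regular medium at 24 h (0.056) or replicate 1 of 130 mM at 24 h (0.085), and members lower ranged from 7 without replicate 2 of uncut 130 mM to 20 without replicate 3 of uncut regular medium. Between 222 mM glucose and regular medium 3082 genes differed, 8724 without the libraries apart, and 5024 without replicate 3 of uncut regular medium and 2054 without replicate 3 of regular medium at 48 h. At 24 h the responses of irf1b (adjusted p = 0.00042), psmb9a (adjusted p = 0.0025) and tnfb (adjusted p = 0.0019) were lower in 222 mM (log2 -2.34 ± 0.39, log2 -3.16 ± 0.66 and log2 -2.11 ± 0.41; psmb9a log2 -4.3 without replicate 2 of 222 mM at 24 h), and at 48 h that of hmgcra (adjusted p = 0.00086) was higher (log2 2.54 ± 0.48).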

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

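The tests of the libraries apart, of their scatter, of unequal depth and of replicate 2 of 222 mM at 3 h were chosen after the results had been seen; those of the uncut baseline, of the clock and of other groupings were written before. In a test of the difference itself, the response differed from that in regular medium in 3605 genes for 130 mM and 3082 for 222 mM. Of 100 assignments of libraries to the media within each time, 2 and 4 gave as many genes, the real one included. The highest others gave 4781 and 5868 genes. Shuffling media within times mixes the medium effect into the response, so these counts cannot test it. For 130 mM the genes with the smallest adjusted p-values by edgeR were the receptor kinase grk5 (3.5e-08), trpv6 (1.5e-05), cel ENSDARG00000029822, ifi46, ctrl, cyt1 and ece2b (1.7e-05 each) and cpa4 (2.3e-05). The response of grk5 was log2 0.83 higher at 3 h and log2 -1.29 and -1.7 lower at 24 and 48 h in 130 mM, while that of cpa4 was log2 2.16 higher and that of ece2b log2 -2.65 lower at 48 h. For 222 mM they were grk5 (3.9e-07), tbxas1 (4.4e-06), hgd, TSTD1, ctss2.1 and slc16a12b (4.9e-06 each), DDX17 (5.1e-06) and vim (7.5e-06). There the response of vim was log2 1.16 higher at 3 h, and those of ctss2.1 and slc16a12b log2 -2.32 lower at 24 h and log2 -2.12 lower at 48 h.

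The first pattern weighed is the 4 libraries apart from their groups. Lower depth is argued against, since the lowest total among them was 0.958 of the mean of the group's others. Each correlated across genes more with another group than with its own: replicate 3 of uncut regular medium with regular medium at 48 h (own minus other -0.56), replicate 3 of uncut 222 mM with 222 mM at 3 h (-0.29), and replicates 1 of regular medium at 3 h and of 130 mM at 24 h with 130 mM at 3 h (-0.33 and -0.09). Of the genes parting the rest of its own group from that group, however, 26.9, 31.7, 21.4 and 55.8% lay nearer its own. The other 32 libraries lay nearer a wrong group for a median of 11.9% (95th percentile 33.5%, highest 68.9%). Single genes went both ways. In replicate 3 of uncut regular medium grk5 kept the label (7.62 CPM against 53.1 to 62.5 at 48 h). There fkbp5 did not (65.3 against 71.5 to 96.4 at 48 h). Another group's label and a difference between the larvae themselves therefore cannot be told apart; of the 36 libraries, replicate 1 of uncut regular medium (-0.05, to 130 mM at 24 h) and replicate 3 of 222 mM at 3 h (-0.09, to uncut 222 mM) were also nearest to another group, and with the labels of the latter and of replicate 3 of uncut 222 mM exchanged 19 genes were called against 180.

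The second pattern is the 7692 genes changed at 3 h in 130 mM against 180 in 222 mM. Scatter of the libraries apart is argued against as its whole cause but not as part of it, since without them the ratio of the counts fell from 42.7 to 2.73 (9824 and 3598 genes), and to between 2.49 and 2.6 with 1 library of uncut 130 mM also left out for equal numbers. A shifted uncut baseline in 130 mM is argued against as the whole cause. Changes from uncut regular medium had a median ratio of 0.727 to those from uncut 130 mM (quartiles 0.518 and 0.924). Unequal depth is argued against too, with mean totals within 1.18 times. Scatter of the 222 mM libraries at 3 h (none left out), a dose difference in the response and any mixture stay open, untested.

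The third pattern is the 19 of 41 clock genes that were higher in 222 mM than in regular medium at 3 h. Replicate 1 of regular medium, which stands apart, is argued against as its cause, since 27 clock genes were called without it, 26 of them higher. Replicate 2 of 222 mM stays open as a source of part of it: 6 were called without that library, and 10 and 8 without replicates 2 and 3 of regular medium, though the 19 genes were all still higher without it, with a median of log2 0.7 against 1.09. Another phase of the clock at sampling may account for it: the 6 genes of the positive limb had a median of log2 -0.03 and the 14 of the opposite phase log2 1.2, a difference of -1.23. Only 1 of the former and 7 of the latter passed, so phase and an effect of glucose cannot be told apart.

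With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so the splits below cannot decide on chance. In uncut larvae 3 splits gave as many genes for 130 mM (real 529, highest other 1723), 2 for 222 mM (2534, 4007) and 1 for 222 against 130 mM (1535, 0). After amputation in regular medium it was 2 at 3 h (3038, 3725), 1 at 24 h (1968, 473) and 1 at 48 h (2925, 2123). In 130 mM it was the real split alone at 3 h (7692, 0), 24 h (538, 2) and 48 h (1236, 0), and in 222 mM 4 at 3 h (180, 2384) and 1 at 24 h (926, 733) and 48 h (3451, 24). Between 130 mM and regular medium it was 1 at each time (1911, 640 at 3 h, 1415, 0 at 24 h and 3999, 0 at 48 h), as between 222 mM and regular medium (4800, 2295 at 3 h, 6862, 0 at 24 h and 3325, 1 at 48 h). The splits with 1723 and 2384 genes, several times the real counts, point to a structure of the samples.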

How the results depend on the processing

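DESeq2, limma on log2(FPKM + 1), the omission of the 4 libraries apart and the block on 2 groups were chosen after the data had been seen, and the other alternatives before. Limma on FPKM with either pseudocount, median-ratio rescaling and the replicate block left all 20 counts within 1.5 times, and so did dropping the expression filter except at 24 h in 130 mM (354). DESeq2 called 910 genes in 130 mM uncut, 1018 and 1884 at 24 and 48 h in 130 mM and 498 at 3 h in 222 mM, and lay within 1.5 times for the other 16 counts. At an adjusted p under 0.01 the tests of the response gave 1010 genes for 130 mM and 958 for 222 mM. No printed gene that passed turned its direction under any alternative; of those that did not pass, il1b and ins at 24 h in 222 mM did with single libraries left out, and ins also on FPKM (log2 0.04 and 0.03). Calls of cxcl8a, il1b, mmp9 and ins changed at 3 h, as given above. With only the 6 libraries compared 51 of the 239 printed gene changes lost their call, as named. Counts rose in other such fits, and in scattered groups the shared fit may understate the spread. For the list tests, the preset correlation of 0.01 moved 357 of 720 past the threshold, limma on log2(FPKM + 0.1) moved 3, and median-ratio rescaling and the block none. No fit varied the depth; on counts simulated at the depth of 130 mM in uncut larvae 20.9% of 1.5-fold changes were recovered. For the counts below, the cause of a change was not tested beyond what each setting leaves out.

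Without the 4 libraries apart, counts moved by over 1.5 times to 5789, 5862 and 2721 in uncut larvae (130 mM, 222 mM and 222 against 130 mM), 5423 and 7594 after amputation in regular medium (24 and 48 h) and 3744 and 4148 after amputation in 130 mM (24 and 48 h). They moved to 3598 and 3625 after amputation in 222 mM (3 and 24 h), 6405, 2228 and 6877 between 130 mM and regular medium (3, 24 and 48 h) and 5900 between 222 mM and regular medium (48 h). The counts became 11179 and 8724 in the differences of response (130 mM and 222 mM). With only the 6 libraries of the groups compared there were 21, 22 and 733 in uncut larvae (130 mM, 222 mM and 222 against 130 mM), 3, 355 and 644 after amputation in regular medium (3, 24 and 48 h) and 6667 after amputation in 130 mM (48 h). In such fits there were 0 and 225 after amputation in 222 mM (3 and 24 h), 0 and 9264 between 130 mM and regular medium (3 and 48 h) and 736 and 8284 between 222 mM and regular medium (3 and 48 h). The 2 counts of 0 come from edgeR, with 1284 genes at an unadjusted p under 0.05 for 3 h in 222 mM and 4286 for 130 mM against regular medium at 3 h. DESeq2 on all libraries called 498 and 2434 there, and limma on log2(FPKM + 1) 122 and 1889. The criterion in the series text, an unadjusted p under 0.05 with a log2 change beyond 1 either way, gave 1096 and 840 in uncut larvae (222 mM and 222 against 130 mM), 761, 748 and 1098 after amputation in regular medium (3, 24 and 48 h) and 2041 and 649 after amputation in 130 mM (3 and 48 h). It gave 347 and 1164 after amputation in 222 mM (3 and 48 h), 678, 680 and 1269 between 130 mM and regular medium (3, 24 and 48 h) and 1542, 2289 and 1098 between 222 mM and regular medium (3, 24 and 48 h). With each library left out in turn, counts ran from 97 to 3635, 1471 to 4232 and 657 to 1780 in uncut larvae (130 mM, 222 mM and 222 against 130 mM), 1990 to 3118, 679 to 3359 and 976 to 5720 after amputation in regular medium (3, 24 and 48 h) and 78 to 1215 and 299 to 663 after amputation in 130 mM (24 and 48 h). They ran from 17 to 1214, 457 to 1660 and 2104 to 3707 after amputation in 222 mM (3, 24 and 48 h), 382 to 4247, 509 to 1462 and 2404 to 2762 between 130 mM and regular medium (3, 24 and 48 h) and 1880 to 2262 between 222 mM and regular medium (48 h). The ranges were 2318 to 7591 and 2054 to 5024 in the differences of response (130 mM and 222 mM).

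The replicate numbers recur in all groups, and a replicate block over all of them gave 456 genes in 130 mM uncut and 159 at 3 h in 222 mM. Deviations from the group means correlated across genes with a median r of -0.002 between libraries of the same number and 0.001 between others, and 9.1% of same-number pairs exceeded 0.1. Of the 36 libraries, 13 had their best match in another group under the same number. All 3 pairs exceeded 0.1 only between uncut larvae and 3 h in 222 mM, where replicates 1 and 2 taken crosswise did too (0.112 and 0.192). A block on these 2 groups gave 312 genes at 3 h in 222 mM, or 26 with only their 6 libraries, and changed no call of a list or printed gene with all libraries in the fit. Of the 4 splits that part all 3 pairs, the real one gave 180 genes and the others at most 19.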

Other observations

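Further lists fixed before the data were examined are given here as values by edgeR, with adjusted p-values of the lists at the estimated correlation, none past the threshold. Of the osmotic stress and osmolyte transport genes, 3 of 36 measured members fell in 130 mM uncut larvae (5 adjusted over the list alone, adjusted p = 0.53; 8 without replicate 3 of uncut regular medium), while 2 rose and 4 fell in 222 mM (2 and 5 adjusted over the list alone, adjusted p = 0.82). At 24 h, 6 of them were higher and 12 lower in 222 mM than in regular medium (also adjusted over the list alone, adjusted p = 0.74). Of the neuron genes, 31 of 59 fell and 1 rose at 3 h in 130 mM glucose (35 and 1 adjusted over the list alone, adjusted p = 0.33), and between 26 and 32 fell with 1 library left out. In the same comparison 25 of 42 enterocyte markers rose (27 adjusted over the list alone, adjusted p = 0.51; 21 to 24 with 1 library left out). Of the red cell genes, 13 of 26 were higher and 1 lower in 130 mM than in regular medium at 48 h (14 and 2 adjusted over the list alone, adjusted p = 0.48; 12 to 13 with 1 library left out).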
